A study of Mus musculus with 8 samples.

How the data were processed

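RNA from whole melanomas of mice was measured in 8 samples on Illumina bead arrays, with 1 biotin-labelled sample on each array. All mice carried BrafCA and Tyr::CreER, in which 4-hydroxytamoxifen painted on the skin of newborns switches on mutant Braf in melanocytes, and tumours were taken 20, 38 or 60 days later. Mice called WT carried the normal type I interferon receptor gene (Ifnar1+/+), and mice called SA carried Ifnar1SA, an allele known to give a receptor chain that resists degradation. The labels' genotype field was followed, since the labels' treatment protocol describes mice with Ifnar1-/- in place of Ifnar1SA. Each of the 4 groups held 2 samples: WT at day 38, and SA at days 20, 38 and 60. The labels do not state whether the samples of a group came from separate mice, so the p-values measure only the spread between these samples.

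The deposited value table held intensities on a linear scale from 183.9 to 71767 for 25697 probes, and its columns were matched to samples by name. The sorted intensities agreed between arrays (medians 409.3 to 410, upper quartile 1352 on every array), from which it was read that the authors had quantile normalized them without subtracting background; GenomeStudio 1.8 is named in the submitters' processing notes. A second table of unnormalized signals with detection p-values was not used. Its 8 signal columns are headed by slide and position on 1 slide, which no label ties to a sample, and its 8 detection columns name no sample. The number of arrays limits the precision.

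The planned background correction and detection filter needed that second table. In their place the deposited intensities were corrected with limma's normexp method (saddle-point fit, offset 16) and put on the log2 scale with no further normalization between arrays, and a probe was kept where its mean log2 value lay above the 40th percentile of all probes (7.24), the fallback that had been set. Gene symbols came from the platform annotation, which gave 23978 probes 1 symbol, 0 several and 1719 none; 0 symbols were changed against the RefSeq gene table of assembly GRCm38.p6, which was also used to place genes on the X and Y chromosomes. Of 16593 distinct genes, the brightest probe past the filter stood for each gene and unnamed probes stood for themselves, which left 11661 measurements to test, 10771 of them with a gene name. Log2 values near the background understate changes, since the offset adds the same amount to every intensity.

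A linear model with 1 mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom and 2.49 from the variance prior). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists, and a list needed 5 measured genes; 34 of the 35 lists were tested, and the list of sex-linked genes was described gene by gene. The result of 1 tested list that was not called, and 1 item of the mouse model and of the naming rule, are not reported here. The lists covered interferon and antigen presentation genes, senescence, cell division, DNA damage, MAPK and stress pathways, metabolism, and markers of the cell types that a melanoma with adjoining skin could hold. Camera with an estimated correlation and fry, which tests whether a list's genes moved on balance in 1 direction without comparing them with other genes, were run beside it. Ranges of a list's median without each array in turn come from the same fit on 7 arrays, in which the group left with 1 array was assumed to vary like the others. Where a comparison does not hold day 20, leaving out either day 20 array gives the same fit. Log2 changes then stay as they were and only the shared variance changes, so genes that pass only there gain no further support.

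The groups, the comparisons, the tests, the gene lists and the alternatives were set before the data were examined, except where a choice is said to have been made later. Genes were named by a rule set then: Ifnar1, Ifnar2 and Braf where measured; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap or, where fewer passed, all that passed and those with the smallest p to a total of 5 in that direction; and, of each list described, up to 4 called members with the largest change or, where 0 passed, the 2 with the smallest p. The alternatives were other background settings, filters and probe rules, a fit on the compared arrays alone, the replicate number as a block, array weights, a variance prior with a trend, other list tests and leaving out each array. A stricter filter and a fit with the array means of the skeletal muscle and adipocyte lists as covariates were added after seeing the data. So was a fit without the genes of the sex chromosomes and without an unnamed probe that followed their pattern.

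The procedure was tested on simulated data for the comparison of SA with WT at day 38, with 200 of 11661 measurements changed in each of 20 simulations. It recovered 33.2% of 2-fold changes, 88.4% of 4-fold changes and 98.3% of 16-fold changes, and 5.13% of its calls were false. A list shifted by 0.8 on the log2 scale was found in 20 of 20 simulations at the preset correlation and in 12 of 20 with an estimated one. The simulated genes varied independently, whereas the estimated correlation of that list, the interferon-stimulated genes, was 0.857 in the data. The simulations therefore do not show how list calls fare at such a correlation. They called a mean of 155.9 genes each, against 7 in the data, so the adjustment over genes was looser there. The shares recovered therefore cannot be carried over to single genes in these data.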

Results

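Gene expression was measured in 8 whole melanomas driven by mutant Braf: 2 WT tumours at day 38 after tamoxifen, and 2 SA tumours each at days 20, 38 and 60, where SA mice carry an interferon receptor allele whose product resists degradation. The title of the series concerns type I interferon signalling, oncogene-induced senescence and melanoma growth. The 4 comparisons below ask how the genotype changed the tumours at day 38 and how SA tumours changed with time. Of 25697 probes, 11661 measurements entered the tests. The pair of WT arrays lay closest together, with a correlation across genes of 0.988 and 160 genes over 2-fold apart. The corresponding values were 0.971 and 591 genes for SA at day 38, 0.970 and 574 for day 60, and 0.944 and 1145 for day 20.

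The Ifnar1 probe read close to background, with a mean log2 intensity of 4.97 ± 0.66 (SD, n = 2) in WT, 4.97 ± 0.15 in SA at day 20, 5.16 ± 0.63 at day 38 and 5.37 ± 0.49 at day 60. It lay below the filter. Since the SA allele changes single residues of the protein, this transcript level checks nothing about the genotype. Ifnar2, the other chain of the receptor, read 9.36 ± 0.18 in WT and 8.89 ± 0.19 in SA at day 38, a difference of −0.47 that was not called (limma, Benjamini-Hochberg adjusted p = 0.371), and 8.70 ± 0.32 and 9.35 ± 0.01 in SA at days 20 and 60. The type I interferon gene Ifnb1 lay below the filter too, at a mean of 6.49 over the arrays. Probes named Braf or Ddx3y were not analysed here.

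Sex-linked transcripts set the SA tumours of day 38 apart from the other 6. Xist, the RNA that silences an X chromosome in females, read 9.44 ± 0.35 (SD, n = 2) in SA at day 38, against 7.0 ± 0.07 in WT and 7.20 ± 0.13 and 7.20 ± 0.51 in SA at days 20 and 60. The Y-linked gene Eif2s3y read 6.15 ± 0.06 in SA at day 38, against 11.70 ± 0.08 in WT, 11.46 ± 0.13 at day 20 and 11.75 ± 0.07 at day 60. Kdm5d, also on the Y chromosome, read 6.31 ± 0.41 in SA at day 38 and 9.15 ± 0.21 in WT. An unnamed probe followed the same pattern (8.75 ± 0.34 and 12.83 ± 0.34). A female pattern at day 38 in SA and a male pattern in the other groups mean that sex cannot be told apart from genotype at day 38, or from day 38 itself in the time course. Days 20 and 60 shared the male pattern.

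**Figure D1:**
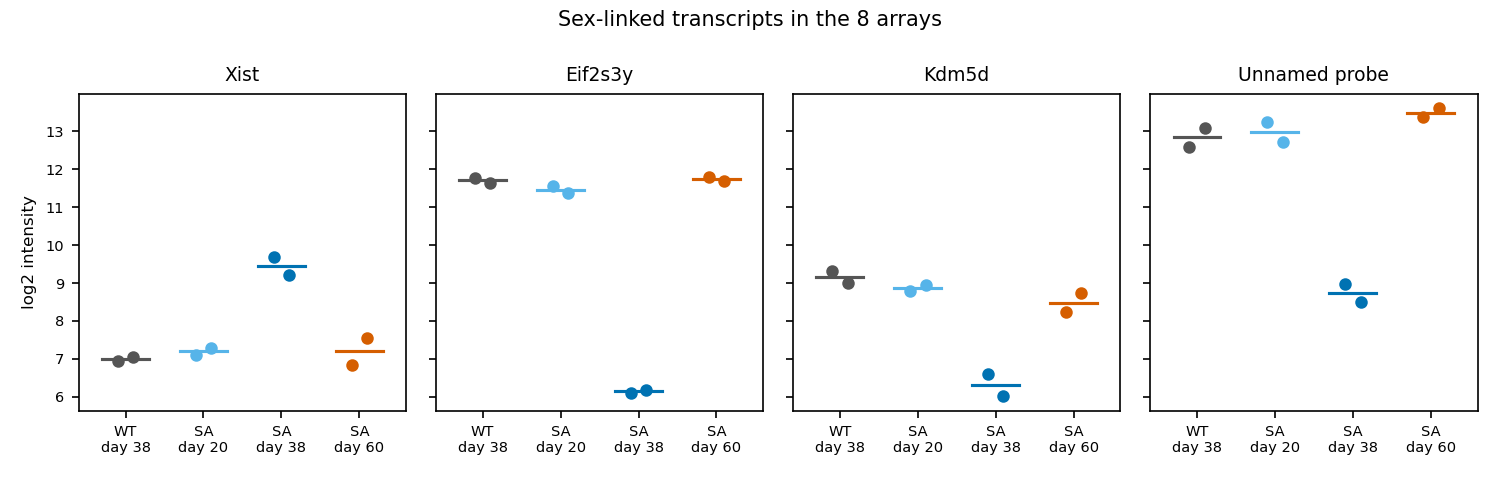
Log2 intensity (vertical axis) of Xist, the Y-linked genes Eif2s3y and Kdm5d, and the unnamed probe that followed them, in the 4 groups. Each point is 1 array and each line a group mean; SA at day 38 stood apart, with Eif2s3y at 6.15 against 11.70 in WT.

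In the comparison of SA with WT tumours at day 38, the 1 time taken from both genotypes, markers of fat and muscle and interferon-stimulated genes were higher in SA as lists. These list calls were lost at adjusted p = 0.586 with an estimated correlation, and 0 muscle or interferon-stimulated genes passed singly. After Benjamini-Hochberg adjustment limma called 7 of 11661 genes, of which 4 rose and 3 fell. Of the 7, 4 were called without background correction and 4 in the deposited values. With the muscle and fat covariates, a fit chosen after seeing the data, 0 were called. Cd1d1, which presents lipids to natural killer T cells, rose by 2.52 (SE 0.18) from a log2 level of 9.67 ± 0.25 (SD, n = 2) to 12.19 ± 0.17, with an adjusted p of 0.0193. The gut hormone gene Pyy rose by 4.24 (SE 0.37, adjusted p = 0.0405) and Smoc1, which encodes a secreted matrix protein, by 3.56 (SE 0.32, adjusted p = 0.0405). Adig, a gene of fat cell formation, rose by 3.38 (SE 0.32, adjusted p = 0.0444). The 3 falls followed sex: Eif2s3y at −5.55 (adjusted p = 8.32e-05), the unnamed probe at −4.09 (0.0193) and Kdm5d at −2.84 (0.0405). The 4 rises compare the same groups, so sex cannot be told apart from genotype for them either. Cd1d1 was also called as falling in SA from day 38 to day 60, where the sex pattern changed as well. Of the 5 genes with the smallest p in each direction, Hcn2 at −2.0 (adjusted p = 0.0703), Arxes2 at 2.21 (adjusted p = 0.0829) and Serpinb6c at −1.91 (adjusted p = 0.11) did not pass, the first 2 of which passed without either day 20 array (adjusted p = 0.0390 and 0.0462). At an unadjusted p under 0.05 there were 1645 genes, where 583 are expected by chance. Leaving out any 1 of the WT, SA day 38 or SA day 60 arrays left limma with 1 gene. Leaving out either day 20 array gave 42, all 7 included. Without the sex chromosomes and the unnamed probe, a fit chosen after seeing the data, limma called 0 genes. In that fit 1577 had an unadjusted p under 0.05. The log2 changes of the 4 rises stayed as they were, while the shared variance and the adjustment over genes changed. Their adjusted p-values became 0.0570 for Cd1d1, 0.0679 for Pyy and Smoc1 and 0.0766 for Adig.

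Markers of fat cells rose in SA tumours at day 38 as a list, with all 15 measured members higher, a median log2 difference of 2.17 and a camera adjusted p of 3.95e-17 (adjusted p = 0.586 with an estimated correlation). Over all genes 1 member, Adig, was called, and 14 rose when adjusted over the list alone. They included the fat hormone genes Adipoq at 3.73 and Lep at 3.66, both named after their values were seen. Skeletal muscle markers rose as well, with a median of 2.68, 25 of 26 members higher, 0 called by limma in either adjustment and an adjusted p of 9.56e-12 (adjusted p = 0.586 with an estimated correlation). Among them Ampd1 differed by 3.85 (SE 0.92, adjusted p = 0.218) and the fast-fibre gene Actn3 by 4.76 (adjusted p = 0.252). Markers of sebaceous glands and epidermal lipid rose with a median of 0.82 in 13 of 14 members and an adjusted p of 6.48e-06, with 0 called over all genes and 4 adjusted over the list alone (Scd1 1.51, Pparg 2.17; adjusted p = 0.586 with an estimated correlation). Scd1 passed over all genes without either day 20 array (adjusted p = 0.0495). Red blood cell genes rose by a median of 1.90 in 7 of 7 members (adjusted p = 0.00831, and adjusted p = 0.586 with an estimated correlation; Hbb-b2 2.52, Alas2 1.96). That call was lost without SA_day38 replicate 1, where the median was 0.44 and the adjusted p 0.241. The fat and sebaceous lists share Pparg and Scd1. Other lists overlap as they were set, among them interferon gamma and class I (Psmb8, Psmb9, Psmb10 and Nlrc5) and cell cycle and DNA damage (Chek1). The list calls are therefore not all separate results.

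Interferon-stimulated genes rose in SA tumours at day 38, with 30 of 31 measured members higher, a median of 0.81 and a camera adjusted p of 1.07e-07 (adjusted p = 0.586 with an estimated correlation). No member passed limma's threshold over all genes or adjusted over the list alone. Lgals3bp, a secreted glycoprotein gene, differed by 1.21 (SE 0.29, adjusted p = 0.218) and the antiviral enzyme gene Oas2 by 2.38 (SE 0.69, adjusted p = 0.257). Genes known to respond to interferon gamma rose by a median of 0.51 in 20 of 21 members (adjusted p = 0.000819, and adjusted p = 0.586 with an estimated correlation; Gbp2 1.01, Cxcl9 1.54). Gbp2 differed by 0.67 without WT_day38 replicate 1. Class I antigen presentation genes rose by 0.45 in 19 of 20 (adjusted p = 0.00137, and adjusted p = 0.586 with an estimated correlation; H2-D1 0.97, H2-Q8 1.10). Dendritic and Langerhans cell and class II genes rose by 0.84 in 12 of 15 members (adjusted p = 0.000784, and adjusted p = 0.586 with an estimated correlation). Of these, 2 were called when adjusted over the list alone, Cd209a at 1.20 and the Langerhans cell gene Cd207 at 1.75. The call of the interferon gamma list was lost without SA_day38 replicate 1 (median 0.29, adjusted p = 0.0509). With the muscle and fat list means as covariates, a fit chosen after seeing the data, the medians of the interferon-stimulated, interferon gamma and class I lists turned to −1.50, −0.88 (adjusted p = 0.0109) and −0.34 (adjusted p = 0.103). Fat and muscle markers and sex differed between the same groups.

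Secreted factors of senescent cells fell in SA tumours at day 38, by a median of 0.35 with 21 of 29 members lower (adjusted p = 0.00831, and adjusted p = 0.586 with an estimated correlation). Over all genes 0 members were called by limma, while adjusted over the list alone 5 fell and 1 rose. Mmp13, a collagenase gene, differed by −1.88 (SE 0.23, adjusted p = 0.11) and the neutrophil attractant Cxcl2 by −2.25 (SE 0.53, adjusted p = 0.218). Without SA_day38 replicate 2 the list's median was −0.19 and its adjusted p 0.0792, and with the muscle and fat covariates the call was lost too (−0.46, adjusted p = 0.0697). The list of senescence regulators and p53 targets was not called (median −0.14, camera adjusted p = 0.457). Its median was −0.04 without SA_day38 replicate 2. Its leading members were Cdkn2b at −1.22 (limma adjusted p = 0.322) and Zmat3 at −0.44 (adjusted p = 0.373). Cell cycle genes rose by a median of 0.24 in 34 of 40 members (adjusted p = 0.000784, and adjusted p = 0.603 with an estimated correlation; Chek1 0.87, Mcm6 0.52). The call was lost without SA_day38 replicate 2 (median 0.06, adjusted p = 0.331), where Chek1 differed by 0.52. Without SA_day38 replicate 1 the median was 0.48, and SA_day38 replicate 2 had the highest array mean of the 8 arrays in both this list (0.68) and the hair follicle list (1.74), a tissue that also divides. Mitochondrial respiration genes rose by 0.24 in 24 of 28 members (adjusted p = 0.000533, and adjusted p = 0.586 with an estimated correlation; Cs 0.60, Ogdh 0.52). Their median was 0.43 without SA_day38 replicate 1, and the call was lost without SA_day38 replicate 2 (median 0.05, adjusted p = 0.272; Cs 0.35). Immediate early and heat shock genes rose by 0.36 in 16 of 19 (adjusted p = 0.00831, and adjusted p = 0.586 with an estimated correlation; Jun −0.45, Klf2 1.36). With the muscle and fat covariates that median turned to −0.49 (adjusted p = 0.0580).

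Melanocyte differentiation and pigment genes rose in SA tumours at day 38 by a median of 0.86 in 14 of 19 members, with an adjusted p of 0.0385 (adjusted p = 0.603 with an estimated correlation). The melanosome transport genes led them in opposite directions, Rab27a at 0.93 (adjusted p = 0.257) and Mlph at −0.87 (adjusted p = 0.308). The call was lost without WT_day38 replicate 2 (adjusted p = 0.0906), SA_day38 replicate 2 (median 0.38, adjusted p = 0.272; Mlph −0.52) or either SA day 60 array (adjusted p = 0.0608). It was also lost without background correction (median 0.44, adjusted p = 0.0629), in the deposited values (0.46, adjusted p = 0.0607) and without the sex chromosomes (0.69, adjusted p = 0.0572). Endothelial markers rose by 0.28 in 16 of 20 members (adjusted p = 0.0385, and adjusted p = 0.586 with an estimated correlation; Flt1 0.74, Tal1 0.53). This call was lost without WT_day38 replicate 1 (median 0.09, adjusted p = 0.358), SA_day38 replicate 1 (median 0.18, adjusted p = 0.286) or either SA day 60 array (adjusted p = 0.0508). It was also lost with all probes tested (0.21, adjusted p = 0.0600), and the median turned to −0.04 with the muscle and fat list means as covariates (adjusted p = 0.887), a fit chosen after seeing the data. Fibroblast and matrix genes fell by a median of 0.31 in 22 of 28 members (adjusted p = 0.0243, and adjusted p = 0.586 with an estimated correlation; Fap −0.83, Fbln1 0.98). The median was −0.58 without SA_day38 replicate 1, and there was no call without WT_day38 replicate 1 (adjusted p = 0.207) or SA_day38 replicate 2 (median −0.09, adjusted p = 0.625), with all probes tested (−0.27, adjusted p = 0.0720) or with those covariates (−0.23, adjusted p = 0.870). Neutrophil markers fell by a median of 0.40 in 12 of 13 members (adjusted p = 0.0373, and adjusted p = 0.586 with an estimated correlation; Stfa1 −0.92, Il1r2 1.63). Their median was −0.65 without WT_day38 replicate 1 and −0.92 without SA_day38 replicate 1. That call was lost without WT_day38 replicate 2 (adjusted p = 0.121), SA_day38 replicate 2 (adjusted p = 0.331) or either day 20 array (adjusted p = 0.0517), with a filter at the 60th percentile (−0.80, adjusted p = 0.0666), with all probes tested (−0.38, adjusted p = 0.0616) and with those covariates (−0.51, adjusted p = 0.444).

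In all, 13 of 34 lists rose and 3 fell at day 38, while camera with an estimated correlation and fry each called 0, with smallest adjusted p-values of 0.586 and 0.104. Without adjustment the former had 1 list and the latter 3 at p under 0.05. Macrophage and monocyte markers were not called (adjusted p = 0.915), with a median of 0.03 and a mean of −0.14, and were led by Clec4d at −1.71 (adjusted p = 0.146) and Ly6c1 at 1.94 (adjusted p = 0.26). The list of interferon receptor pathway genes had a median of 0.00 (adjusted p = 0.67; Usp18 1.91, Ifnar2 −0.47). T cell (median 0.10, adjusted p = 0.0821), cytotoxic lymphocyte (0.39, adjusted p = 0.273), B cell (0.29, adjusted p = 0.143) and mast cell (0.40, adjusted p = 0.115) lists did not pass either. Nor did the lists for hair follicle (0.39, adjusted p = 0.102), keratinocytes (0.06, adjusted p = 0.477), neural crest (−0.26, adjusted p = 0.407), Schwann cells (−0.46, adjusted p = 0.171) and cartilage (0.13, adjusted p = 0.46). Medians of the pathway lists not called were −0.06 for MAPK output (adjusted p = 0.915), 0.14 for DNA damage (adjusted p = 0.0541), 0.13 for hypoxia (adjusted p = 0.143), 0.17 for the unfolded protein response (adjusted p = 0.143) and 0.04 for ribosomal proteins (adjusted p = 0.106). Median, mean and test differed in sign for the macrophage, MAPK, keratinocyte and cartilage lists.

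**Figure D2:**
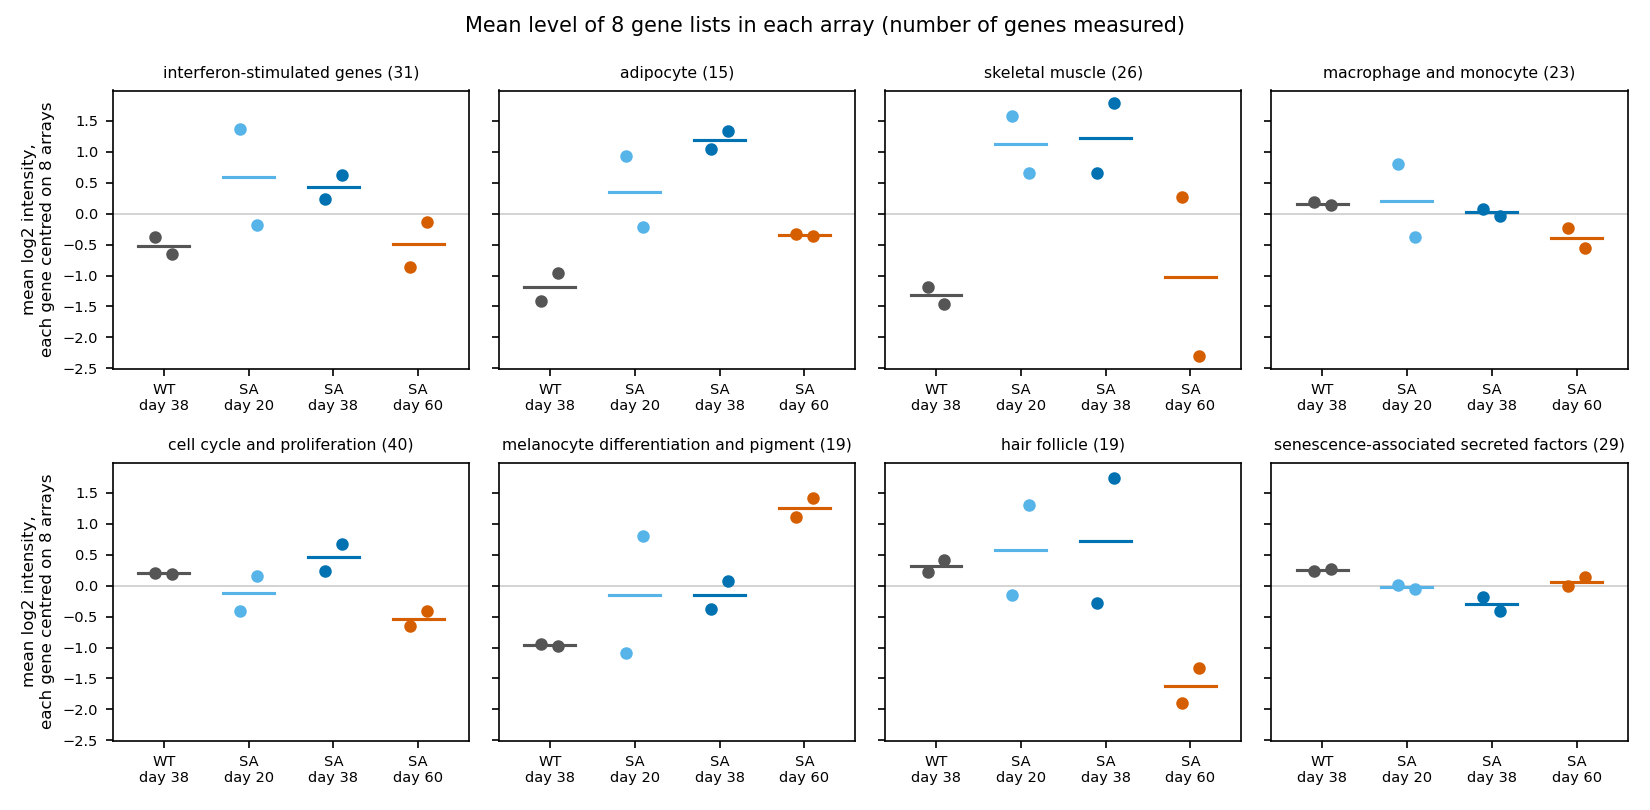
Mean log2 intensity of 8 gene lists in each array (vertical axis), with each gene centred on its mean over the 8 arrays. Each point is 1 array and each line a group mean; the group means of fat and muscle markers were lowest in WT, although SA_day60 replicate 2 was the lowest single array in muscle (−2.30), and the group mean of melanocyte genes was highest in SA at day 60, where their array means were 1.10 and 1.41.

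From day 20 to day 38 in SA tumours, genes of cell division were higher and keratinocyte and epidermis genes lower as lists. These calls were lost with an estimated correlation (adjusted p = 0.937 and adjusted p = 0.447), and 0 of 40 cell cycle genes passed singly. The only genes called by limma with Benjamini-Hochberg adjustment, 2 of 11661, were the sex-linked Eif2s3y, which fell by 5.31 (SE 0.15, adjusted p = 0.000111), and the unnamed probe, which fell by 4.23 (SE 0.28, adjusted p = 0.0161). Of the 5 genes with the smallest p in each direction, the other 8 did not pass. The falls were the cornified envelope genes Lce1b at −1.54 and Lce1l at −2.33 and Serpina12 at −2.66, each with an adjusted p of 0.0544, and all 3 passed without either day 20 array (adjusted p = 0.0185 to 0.0420). The rises were Pyy at 3.58 (adjusted p = 0.0544, and 0.0384 without SA_day20 replicate 2), Cd1d1 at 1.60 (adjusted p = 0.0631), Xist at 2.24 (0.0762), Usp11 at 1.16 (0.0778) and Arxes2 at 1.64 (0.0967). Ifnar2 differed by 0.19 (adjusted p = 0.78), by −0.03 and 0.41 without SA_day20 replicates 1 and 2, and by 0.05 and 0.33 without SA_day38 replicates 1 and 2. At an unadjusted p under 0.05 there were 1249 genes, of which 693 were lower at day 38. Limma called 46 genes without SA_day20 replicate 1, 39 without SA_day20 replicate 2, 2 without SA_day38 replicate 2 and 1 without any other array. With the sex chromosomes left out it called 0, with 1196 at an unadjusted p under 0.05.

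Cell cycle genes rose between day 20 and day 38 by a median of 0.62, with 39 of 40 members higher and an adjusted p of 9.07e-12 (adjusted p = 0.937 with an estimated correlation). None passed singly over all genes or adjusted over the list alone. The cyclin gene Ccne2 differed by 0.81 (adjusted p = 0.277) and the replication helicase gene Mcm4 by 0.67 (adjusted p = 0.295). The median was 0.39 without SA_day38 replicate 2 and 0.28 without SA_day20 replicate 1. DNA damage response genes rose by 0.29 in 15 of 16 members (adjusted p = 0.00208, and adjusted p = 0.937 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone (Chek2 0.93, Rad54l 0.95). Without SA_day38 replicate 1 that median was 0.50, and without SA_day38 replicate 2 it was 0.16 and not called (adjusted p = 0.0785). A filter at the 60th percentile lost the call as well (0.20, adjusted p = 0.0660). Keratinocyte and epidermis genes fell by a median of 0.46 in 25 of 32 members (adjusted p = 1.33e-05, and adjusted p = 0.447 with an estimated correlation). Adjusted over the list alone 1 was called, Lce1b, and the desmosome gene Dsc1 followed at −0.96 (adjusted p = 0.288). Their median was −0.29 without SA_day20 replicate 2, and with the muscle and fat covariates it was −0.17 and the call was lost (adjusted p = 0.0526).

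Neural crest genes rose from day 20 to day 38 by a median of 0.74 in 14 of 16 members (adjusted p = 0.00462, and adjusted p = 0.937 with an estimated correlation). They were led by the nerve growth factor receptor gene Ngfr at 1.55 (adjusted p = 0.229) and Gfra3 at 3.47 (adjusted p = 0.342), with 0 called over all genes and 1 adjusted over the list alone. Ngfr differed by 1.03 without SA_day20 replicate 1 and 2.07 without replicate 2 (adjusted p = 0.0389). The list's call was lost without SA_day38 replicate 1 (median 0.45, adjusted p = 0.059) or SA_day20 replicate 1 (median 0.22, adjusted p = 0.251). The median was 1.13 without SA_day38 replicate 2 and 1.37 without SA_day20 replicate 2. Adipocyte markers rose by 0.64 in 13 of 15 members (adjusted p = 0.00208, and adjusted p = 0.937 with an estimated correlation; Lep 2.80, Thrsp 1.96), with 0 called over all genes and 1 adjusted over the list alone. The adipocyte call was lost without SA_day38 replicate 2 (adjusted p = 0.0518) or SA_day20 replicate 2 (median 0.24, adjusted p = 0.337), and its median was 0.98 without SA_day20 replicate 1. Thrsp differed by 3.12 without SA_day20 replicate 1 (adjusted p = 0.0145) and 0.80 without replicate 2 (adjusted p = 0.214). In all 4 lists rose and 1 fell at the preset correlation, and 0 with an estimated correlation or by fry (smallest adjusted p-values 0.447 and 0.116; 1 and 2 lists without adjustment).

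Several lists between day 20 and day 38 hung on single arrays of day 20, whose members lay far apart. Interferon-stimulated genes were not called (median −0.16, adjusted p = 0.358; Bst2 −0.73, Eif2ak2 −0.60), but their median was 0.58 without SA_day20 replicate 1 (adjusted p = 1.31e-05) and −0.93 without SA_day20 replicate 2 (adjusted p = 1.42e-09). Bst2 and Eif2ak2 differed by 0.17 and 0.20 without SA_day20 replicate 1, −1.64 and −1.41 without replicate 2, and −0.41 and −0.36 without SA_day38 replicate 1. Melanocyte genes had a median of −0.00 (adjusted p = 0.402; Gpnmb −1.29, Mitf −0.83), which was −0.85 without SA_day20 replicate 1 (adjusted p = 2.77e-08) and 0.64 without SA_day20 replicate 2 (adjusted p = 0.00278). The median was 0.04 without SA_day38 replicate 1 and 0.72 with the muscle and fat covariates, and called in neither. Mitf differed by −1.28 and −0.39 without SA_day20 replicates 1 and 2, and Gpnmb by −0.82 without SA_day20 replicate 2 and −0.79 without SA_day38 replicate 1. Secreted factors of senescence (median −0.09, adjusted p = 0.3), senescence and p53 genes (−0.07, adjusted p = 0.454, and 0.03 without SA_day38 replicate 2) and skeletal muscle markers (0.03, adjusted p = 0.93) were not called. Median, mean and test differed in sign for the class II list (median 0.06, mean −0.02) and the endothelial list (median 0.03), neither of them called.

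From day 38 to day 60 in SA tumours, cell division genes, hair follicle markers and fat and muscle markers were lower as lists and pigment cell genes higher. These list calls were lost at adjusted p = 0.671 with an estimated correlation, and 0 members of the hair follicle and muscle lists passed singly over all genes. Limma with Benjamini-Hochberg adjustment called 127 of 11661 genes, of which 83 rose and 44 fell. Of these, 112 had a name, and 7 lay on the X and 2 on the Y chromosome. Mitf, the master transcription factor of melanocytes, rose by 2.45 (SE 0.33, adjusted p = 0.042) from 7.76 ± 0.23 (SD, n = 2) to 10.21 ± 0.39. Among the other large rises were the synaptic membrane gene Tmem179 at 3.78 (SE 0.47, adjusted p = 0.042), the zinc-binding glycoprotein gene Azgp1 at 2.72 (SE 0.32, adjusted p = 0.042), the apolipoprotein gene Apoc4 at 2.61 (adjusted p = 0.0447), the myeloid lectin Clec4d at 2.45 (adjusted p = 0.0343) and the phosphatase gene Dusp3 at 2.01 (adjusted p = 0.0447). Nr1d1, a repressor of the circadian clock, rose by 2.55 (SE 0.25, adjusted p = 0.0343). The sex-linked Eif2s3y (5.60), unnamed probe (4.74) and Kdm5d (2.17) completed the 10 largest rises. Different probes gave 0.61 to 2.72 for Azgp1, 0.16 to 2.01 for Dusp3 and 2.55 to 2.87 for Nr1d1. Ifnar2 differed by 0.46 and was not called (adjusted p = 0.214).

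The largest fall from day 38 to day 60 was that of Retnla, a marker of alternatively activated macrophages that fat tissue also makes, from a log2 level of 14.80 ± 0.59 (SD, n = 2) to 8.15 ± 0.33, a change of −6.65 (SE 0.80, limma adjusted p = 0.042). Other falls were those of the fat hormone gene Lep (−4.53), the kinase gene Pdk4 (−3.23), Angptl4 (−2.63) and the lipoprotein lipase gene Lpl (−2.34), with adjusted p-values from 0.042 to 0.0447. The hair keratin genes Krtap1-5 (−4.76) and Krt26 (−4.08) fell, as did Fcrls (−3.29) and Itm2a (−3.10). Cd1d1 changed by −2.56 (SE 0.18, adjusted p = 0.0175). At an unadjusted p under 0.05 there were 3047 genes. Without any 1 of the WT, SA day 38 or SA day 60 arrays limma called 1 or 2 genes, and without either day 20 array 930, all 127 included. Without a filter on dim probes it called 3, in the fit on the compared arrays alone 44, and without the sex chromosomes, a fit chosen after seeing the data, 113, all of them among the 127. With the muscle and fat covariates, also chosen after seeing the data, it called 0. Without background correction it called 390, and in the deposited values 365.

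Cell cycle genes fell from day 38 to day 60 by a median of 1.02, with 38 of 40 members lower and a camera adjusted p of 3.82e-15 (adjusted p = 0.671 with an estimated correlation). Over all genes 3 fell, the mitotic motor gene Kif11 (−1.503), Cdca8 of the chromosomal passenger complex (−1.495) and Ccne2 (−1.41). Adjusted over the list alone 32 fell and 1 rose, the cyclin gene Ccnd1 at 1.05. Hair follicle markers fell in the same arrays, with array means of −0.29 and 1.74 at day 38 and −1.90 and −1.34 at day 60, beside 0.23 and 0.68 and then −0.66 and −0.41 for the cell cycle list. DNA damage response genes fell by a median of 0.39 in 12 of 16 members (adjusted p = 0.0173, and adjusted p = 0.671 with an estimated correlation), with Fancd2 called at −1.23 over all genes and 4 falls and 1 rise adjusted over the list alone. That call was lost without SA_day38 replicate 2 (median −0.26, adjusted p = 0.0815) or SA_day60 replicate 1 (median −0.27, adjusted p = 0.0999), and with a filter at the 60th percentile (median −0.20, adjusted p = 0.399). Senescence and p53 genes were not called as a list (median 0.22, camera adjusted p = 0.315, and median 0.14 without SA_day60 replicate 1). Of them Lmnb1, a nuclear lamina gene whose loss marks senescent cells, fell by 1.38 (SE 0.21, adjusted p = 0.0447), and adjusted over the list alone 1 fell and 1 rose. Secreted factors of senescence had a median of 0.06 and a mean of 0.36 (adjusted p = 0.504). The median was −0.03 without SA_day38 replicate 2 and 0.37 without SA_day38 replicate 1, with 0 called over all genes and 3 rises and 1 fall adjusted over the list alone (Plaur 1.28, Timp1 3.05). Plaur differed by 0.83 without SA_day60 replicate 1, and Timp1 passed without either day 20 array (adjusted p = 0.0229). MAPK output genes had a median of 0.54 (adjusted p = 0.0732; Ier3 1.88, Ccnd1 1.05).

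Melanocyte differentiation and pigment genes rose from day 38 to day 60 by a median of 1.19 in 18 of 19 members (adjusted p = 0.000107, and adjusted p = 0.671 with an estimated correlation). Mitf was called over all genes and 6 rose when adjusted over the list alone, among them the melanocortin receptor gene Mc1r at 1.84 and Gpnmb at 2.14, both named after their values were seen. With the muscle and fat list means as covariates, a fit chosen after seeing the data, the median of this list turned to −0.24 (adjusted p = 0.687), and the sex pattern changed between the same groups. Hair follicle genes fell by a median of 2.95 in 19 of 19 members (adjusted p = 2.36e-07, and adjusted p = 0.671 with an estimated correlation; Krt72 −2.94, Krtap9-3 −3.45). Over all genes 0 were called and 11 adjusted over the list alone, although Krt72 and Krtap9-3 passed without either day 20 array (adjusted p = 0.0330 and 0.0151). The list's median was −1.93 without SA_day38 replicate 2. Skeletal muscle markers fell by 2.22 in 24 of 26 members (adjusted p = 8.31e-07, and adjusted p = 0.671 with an estimated correlation; Ampd1 −4.24, Tnnt3 −3.29), none of them singly over all genes or adjusted over the list alone. Tnnt3 differed by −1.97 without SA_day60 replicate 2 (adjusted p = 0.133), and Ampd1 passed without either day 20 array (adjusted p = 0.0348). The muscle median was −3.90 without SA_day60 replicate 1 and −0.97 without SA_day60 replicate 2, the array with the lowest muscle mean (−2.30, against 0.27 in the other array of day 60). Adipocyte markers fell by 0.93 in 15 of 15 members (adjusted p = 5.43e-06, and adjusted p = 0.671 with an estimated correlation). Over all genes 2 were called, Lep and Lpl, and 7 adjusted over the list alone, with a median of −1.45 without SA_day38 replicate 1. Keratinocyte genes were not called as a list (median −0.05, adjusted p = 0.299), but Sprr1a fell by 1.79 and Lce1b rose by 0.86.

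Interferon-stimulated genes fell from day 38 to day 60 by a median of 1.03 in 30 of 31 members (adjusted p = 2.23e-05, and adjusted p = 0.724 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone. The viral RNA sensor gene Ddx58 differed by −0.57 (SE 0.19, adjusted p = 0.122) and Samd9l by −1.07 (SE 0.38, adjusted p = 0.145). The list's median was −0.50 without SA_day60 replicate 1. Class I antigen presentation genes fell by 0.37 in 19 of 20 members (adjusted p = 0.00316, and adjusted p = 0.677 with an estimated correlation; Pdia3 −0.49, H2-M3 −1.72). They had a median of −0.62 without SA_day60 replicate 2, and no call without SA_day60 replicate 1 (median −0.12, adjusted p = 0.12). Interferon gamma genes fell by 0.46 in 17 of 21 (adjusted p = 0.0036, and adjusted p = 0.724 with an estimated correlation; Gbp3 −1.86, Gbp2 −1.43). These 2 genes and H2-M3 passed singly without either day 20 array, which left their log2 changes as they were and altered only the shared variance. The list's call was lost without SA_day38 replicate 1 (adjusted p = 0.0629) or SA_day60 replicate 1 (median −0.20, adjusted p = 0.113), while the median was −0.75 without SA_day38 replicate 2 and −1.11 without SA_day60 replicate 2. Dendritic cell and class II genes fell by 1.01 in 12 of 15 members (adjusted p = 0.0036, and adjusted p = 0.671 with an estimated correlation). The dendritic lectin Cd209a was called at −1.61, with 3 falls adjusted over the list alone. Their call was lost without SA_day38 replicate 1 (median −0.57, adjusted p = 0.0629), and the median was −0.50 without SA_day60 replicate 1. Macrophage markers were not called (median −0.48, adjusted p = 0.0842). These falls stood beside those of fat and muscle markers and beside the change of sex, and with the muscle and fat covariates the medians of the interferon-stimulated and interferon gamma lists turned to 0.40 and 0.24 and the class I call was lost (−0.03, adjusted p = 0.839).

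Of 34 lists, 1 rose and 9 fell from day 38 to day 60, while camera with an estimated correlation and fry called 0 each, with smallest adjusted p-values of 0.671 and 0.203 and with 0 and 7 lists at an unadjusted p under 0.05. The fibroblast (median −0.11, adjusted p = 0.494), sebaceous (−0.05, adjusted p = 0.824), neutrophil (0.08, adjusted p = 0.504) and interferon receptor pathway (−0.04, adjusted p = 0.614) lists were not called. For the last 3 of these, median, mean and test differed in sign.

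**Figure D3:**
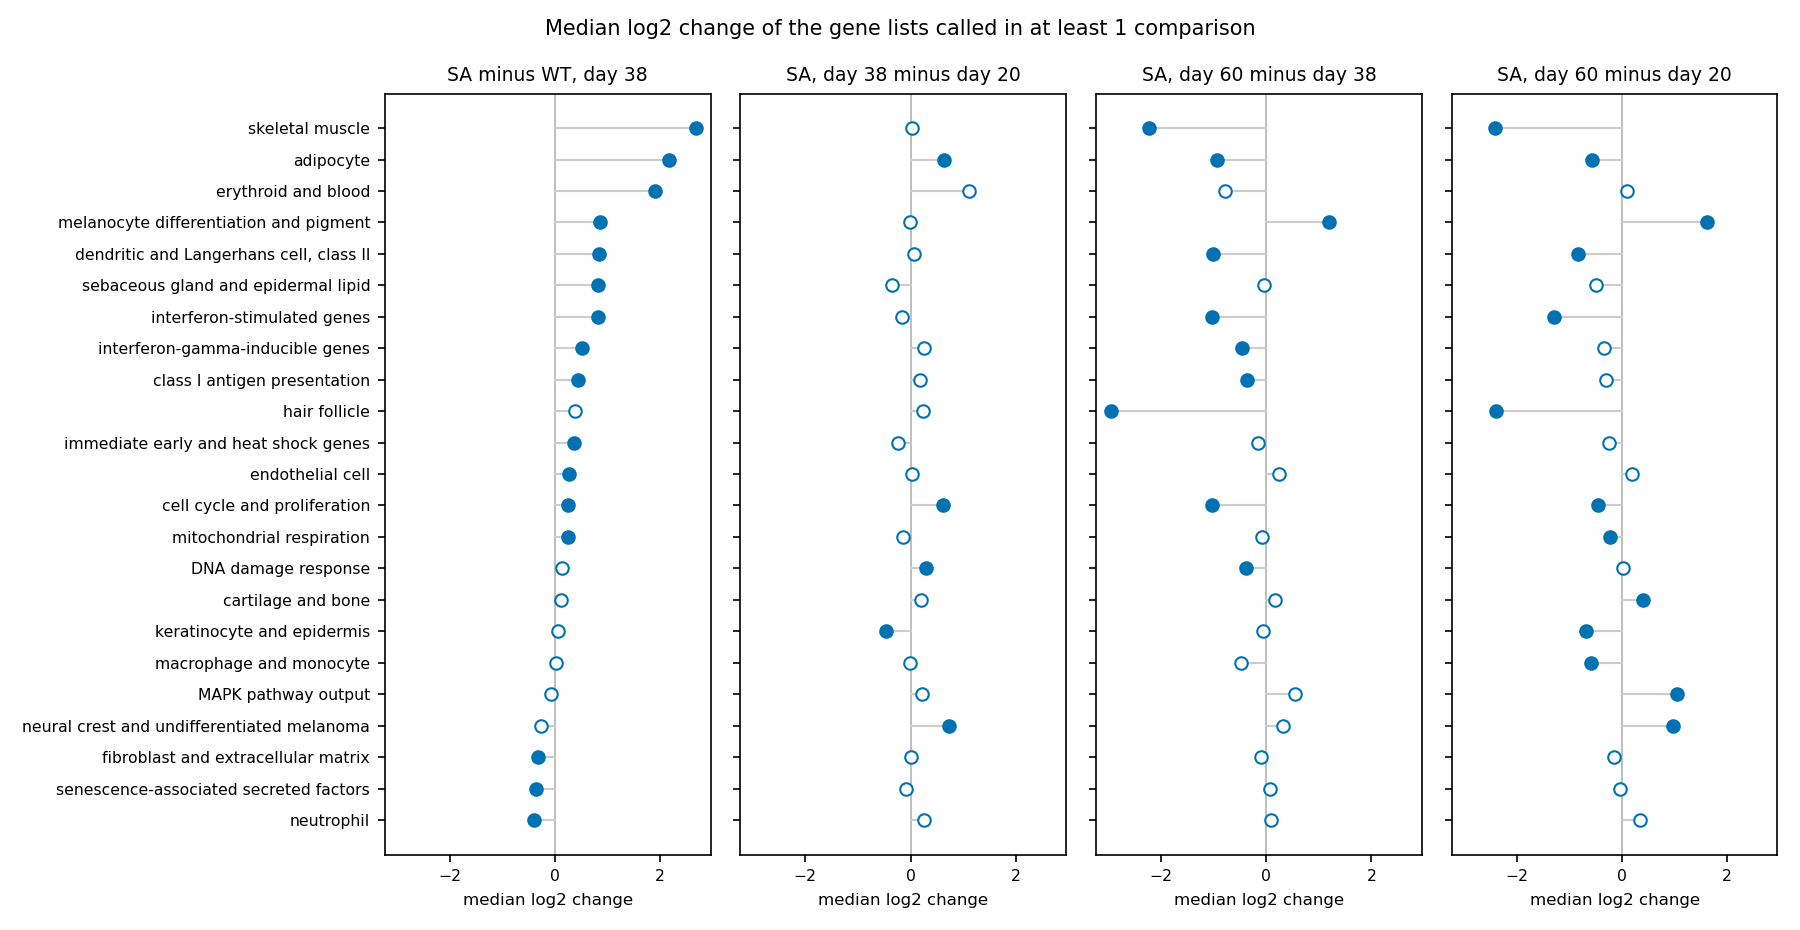
Median log2 change (horizontal axis) of the 23 gene lists that camera called in at least 1 of the 4 comparisons, at the preset correlation. Filled points mark lists called in that comparison and open points lists not called; hair follicle genes had the lowest median from day 38 to day 60, −2.95.

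Between day 20 and day 60, the pair of SA groups that shared the male pattern of sex-linked genes, interferon-stimulated, epidermal, hair, fat and muscle genes were lower at day 60 and pigment cell and MAPK output genes higher, as lists. These calls were all lost with an estimated correlation, at adjusted p-values of 0.371 to 0.791. Limma with Benjamini-Hochberg adjustment called 0 of 11661 genes, with 2741 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0756. The genes with the smallest p all stood at that value and did not pass: Azgp1 at 2.98, Timp3, an inhibitor of matrix proteases, at 1.86, Cstdc4 at 1.41, and unnamed probes at 1.31 and 1.47, against Cd209a at −1.72, Cysrt1 at −1.61, Trex2 at −1.55, Gramd3 at −1.27 and Gm94 at −2.13. These genes passed without SA_day20 replicate 2 but not without SA_day20 replicate 1, and either fit leaves day 20 with 1 array. Ifnar2 differed by 0.65 (adjusted p = 0.144), and by 0.43 without SA_day20 replicate 1. Leaving out SA_day20 replicate 2 gave 915 called genes and leaving out SA_day20 replicate 1 gave 6, while leaving out any other array gave 0, with 1864 to 2679 at an unadjusted p under 0.05.

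Interferon-stimulated genes fell from day 20 to day 60 by a median of 1.28 in 30 of 31 members (adjusted p = 2.66e-07, and adjusted p = 0.791 with an estimated correlation; Ddx58 −0.65, Mx1 −0.94). Their median was −0.43 without SA_day20 replicate 1, −2.19 without SA_day20 replicate 2 and −0.70 without SA_day60 replicate 1. Mx1 differed by −0.59 without SA_day20 replicate 1, and Ddx58 by −0.86 without replicate 2 (adjusted p = 0.0478). Keratinocyte genes fell by 0.67 in 24 of 32 members (adjusted p = 1.53e-06, and adjusted p = 0.371 with an estimated correlation; fry's adjusted p was 0.0513). Of these, 8 fell when adjusted over the list alone (Dsc1 −1.98, Sprr1a −1.63). Without SA_day20 replicate 2 the median was −0.44, and Dsc1 at −1.81 and Sprr1a at −1.39 passed over all genes (adjusted p = 0.0269 and 0.0308). Hair follicle genes fell by 2.40 in 18 of 19 members (adjusted p = 4.13e-07, and adjusted p = 0.791 with an estimated correlation; Krtap9-3 −3.30, Krt27 −3.51), with 10 adjusted over the list alone, and Krtap9-3 was −2.33 without SA_day20 replicate 2 (adjusted p = 0.0329). Skeletal muscle markers fell by 2.40 in 26 of 26 (adjusted p = 2.55e-07, and adjusted p = 0.791 with an estimated correlation; Tnnt1 −2.43, Tnnt3 −2.81). Without SA_day60 replicate 2 the median was −0.82 and Tnnt3 differed by −1.49. Adipocyte markers fell by 0.57 in 14 of 15 members (adjusted p = 0.00498, and adjusted p = 0.791 with an estimated correlation; Lpl −1.65, Lep −1.73), with 1 adjusted over the list alone. The median was −1.04 without SA_day20 replicate 2, where Lpl at −2.09 passed (adjusted p = 0.0104). The call was lost without SA_day20 replicate 1 (median −0.01, adjusted p = 0.673; Lep −1.12). Dendritic cell and class II genes fell by 0.83 (adjusted p = 0.00498, and adjusted p = 0.791 with an estimated correlation; Cd209a −1.72, Cd74 −1.39). They had a median of −1.25 without SA_day60 replicate 2 and no call without SA_day60 replicate 1 (median −0.40, adjusted p = 0.0515). Macrophage markers fell by 0.58 (adjusted p = 0.0124, and adjusted p = 0.791 with an estimated correlation; Lyz2 −0.93, Chil3 1.89). This was a call lost without SA_day20 replicate 1 (median −0.17, adjusted p = 0.682) or SA_day60 replicate 2 (median −0.35, adjusted p = 0.276), with a median of −1.10 without SA_day20 replicate 2. Chil3 differed by 1.21 without SA_day60 replicate 1, and Lyz2 by −1.17 without SA_day20 replicate 2 (adjusted p = 0.0262). With the muscle and fat list means as covariates, a fit chosen after seeing the data, the macrophage median turned to 0.16 (adjusted p = 0.485).

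Melanocyte genes rose from day 20 to day 60 by a median of 1.62 in 18 of 19 members (adjusted p = 0.000273, and adjusted p = 0.791 with an estimated correlation; Mitf 1.62, Mc1r 1.85), with 1 called when adjusted over the list alone. The median was 2.47 without SA_day20 replicate 2, where Mitf at 2.07 and Mc1r at 2.47 passed (adjusted p = 0.0201 and 0.0219), and the call was lost without SA_day20 replicate 1 (median 0.46, adjusted p = 0.0674; Mc1r 1.22). Neural crest genes rose by 0.97 in 15 of 16 members (adjusted p = 0.00505, and adjusted p = 0.791 with an estimated correlation; Tfap2b 1.84, Nes 2.60), with medians of 0.42 and 1.65 without SA_day20 replicates 1 and 2. Tfap2b and Nes differed by 1.20 and 1.502 without SA_day20 replicate 1, and by 2.48 and 3.70 without replicate 2 (adjusted p = 0.0193 and 0.0213). MAPK output genes rose by 1.04 in 14 of 17 members (adjusted p = 0.00505, and adjusted p = 0.791 with an estimated correlation), with 2 adjusted over the list alone, Ccnd1 at 1.66 and Ier3 at 1.78, and a median of 0.54 without SA_day20 replicate 1. Ier3 differed by 1.14 without that array, and without SA_day20 replicate 2 Ccnd1 at 2.13 and Ier3 at 2.42 passed over all genes (adjusted p = 0.0152 and 0.0158). With the muscle and fat covariates the melanocyte, neural crest and MAPK calls were all lost (medians 0.57, 0.22 and 0.40; adjusted p = 0.231, 0.485 and 0.229). Cell cycle genes fell by 0.46 in 33 of 40 members (adjusted p = 1.72e-05, and adjusted p = 0.791 with an estimated correlation; Cdca3 −0.96, Ccnd1 1.66), with 1 fall and 1 rise adjusted over the list alone. They had a median of −0.72 without SA_day20 replicate 1, and no call without SA_day20 replicate 2 (median −0.13, adjusted p = 0.118). Mitochondrial genes fell by 0.23 in 25 of 28 members (adjusted p = 0.00176, and adjusted p = 0.791 with an estimated correlation; Atp5j −0.55, Sdhb −0.67), a call lost without SA_day20 replicate 2 (median −0.14, adjusted p = 0.137) and with those covariates (median −0.12, adjusted p = 0.0950). Cartilage and bone genes rose by 0.41 in 12 of 13 members (adjusted p = 0.0182, and adjusted p = 0.783 with an estimated correlation; Sp7 1.34, Comp 0.77), and Comp differed by 0.49 without SA_day60 replicate 1. This call was lost without SA_day20 replicate 1 (adjusted p = 0.0674) or SA_day60 replicate 2 (adjusted p = 0.104). It was also lost without background correction (0.25, adjusted p = 0.0507), without a filter on dim probes (0.15, adjusted p = 0.206) and with those covariates (median 0.11, adjusted p = 0.241).

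The senescence and p53 list had a median of 0.15 from day 20 to day 60 (camera adjusted p = 0.821). Its median was 0.068 without SA_day20 replicate 2 and 0.071 without SA_day60 replicate 1. The list was led by Cdkn2a, which encodes the senescence effectors p16 and p19, at 3.11 (SE 0.74, limma adjusted p = 0.108). The arrays of day 20 read 5.58 and 7.88 for it, and the difference was 1.96 without SA_day20 replicate 1 (adjusted p = 0.187) and 4.26 without SA_day20 replicate 2 (adjusted p = 0.0152). A second Cdkn2a probe gave 0.71, so the size of this difference is uncertain. Secreted factors of senescence had a median of −0.03 and a mean of 0.09 (adjusted p = 0.94; Il1a −1.41, and −1.64 with adjusted p = 0.0329 without SA_day20 replicate 2; Mmp9 −1.12), with 0 called over all genes and 2 rises and 3 falls adjusted over the list alone. Their median was 0.23 without SA_day20 replicate 1 or 0.41 without SA_day60 replicate 1. Of 34 lists 4 rose and 9 fell, and camera with an estimated correlation and fry called 0 each, with smallest adjusted p-values of 0.371 and 0.0513 and with 2 and 5 lists at an unadjusted p under 0.05. Class I (median −0.30, adjusted p = 0.0638) and interferon gamma genes (−0.35, adjusted p = 0.0672) were not called. Median, mean and test differed in sign for 7 lists, 0 of them called, among them secreted factors of senescence and the Schwann cell, neutrophil, DNA damage, unfolded protein and interferon receptor lists.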

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

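Of the settings here, the 60th percentile filter, the fit without sex chromosomes and the fit with muscle and fat covariates were chosen after seeing the data. Called genes (SA against WT at day 38; day 20 to 38; day 38 to 60; 20 to 60) numbered 7, 2, 127 and 0, and called lists 16, 5, 10 and 13. Without background correction they numbered 4, 21 and 390, and in the deposited values on the log2 scale 4, 21 and 365, with the 20 to 60 count at 0 and all 127 kept. An offset of 50 gave 10 for day 20 to 38, a trend in the variance prior 14, and array weights 13 for SA against WT. Without a dim probe filter 3 genes were called from day 38 to 60, and the 60th percentile filter gave 15 and 332 for the middle comparisons, 102 of them among the 127. All probes tested gave 269 probes from day 38 to 60 and 10 lists from day 20 to 38. The compared arrays alone gave 36, 1 and 44. Without sex chromosomes the first pair of counts was 0 and 0 (limma; 1577 and 1196 unadjusted). Camera with an estimated correlation and fry called 0, 0, 0 and 0 lists (unadjusted 1, 1, 0 and 2, and 3, 2, 7 and 5), so of the 44 list calls 0 held there; 44 held with array weights, a trend, an offset of 50 and the compared arrays alone, and 43, 42, 43, 41, 39 and 43 with the deposited values, no background correction, no filter, all probes, the 60th percentile filter (which left 2 lists untested) and no sex chromosomes. The calls lost there were, for SA against WT, melanocyte (medians 0.44, 0.46 and 0.69 with no background correction, the deposited values and no sex chromosomes), neutrophil (−0.80 and −0.38 with the 60th percentile and all probes), fibroblast and endothelial (−0.27 and 0.21 with all probes). Otherwise they were DNA damage from day 20 to 38 and day 38 to 60 (0.20 and −0.20 with the 60th percentile) and cartilage from day 20 to 60 (0.25 and 0.15 with no background correction and no filter). Where not shown by construction, the cause was not tested.

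With the replicate number as a block, limma called 1, 1, 1 and 0 genes, and all 44 list calls held. Same-numbered arrays of different groups did not deviate together (correlations of −0.196 to 0.107, and 0 of 8 arrays closest to their own number). This gave no sign that the numbers pair the samples, but 1 difference in each group cannot exclude it.

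Without each array in turn, called genes ranged from 1 to 42, 1 to 46, 1 to 930 and 0 to 915, and lists from day 20 to 38 from 5 to 11. Leaving out an array of day 20, the most variable group, gave the highest counts. Of 35 named gene calls, 31 were lost without either WT array, 32 without any 1 of the SA day 38 and day 60 arrays and 0 without either day 20 array. From day 20 to 38, medians ranged from −0.93 to 0.58 for interferon-stimulated genes, −0.85 to 0.64 for melanocyte genes (0.0033 with no filter) and −0.16 to 0.027 for senescence and p53 genes, and single genes from −0.033 to 0.41 (Ifnar2), −1.64 to 0.17 (Bst2) and −1.41 to 0.20 (Eif2ak2). Secreted factors of senescence ranged from −0.025 to 0.37 from day 38 to 60 and from −0.080 to 0.41 from day 20 to 60.

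With the muscle and fat list means as covariates, which left 2 residual degrees of freedom, limma called 0, 1 and 0 genes (982 and 1457 unadjusted for the counts of 0) and camera 10 lists from day 20 to 38 and 8 from day 20 to 60. Of 44 list calls 18 held, 12 were lost and 14 turned. The lost ones were, for SA against WT, secreted factors of senescence (−0.46, adjusted p = 0.0697), neutrophil (−0.51, 0.444), fibroblast (−0.23, 0.870) and muscle (0.45, 0.806); from day 20 to 38 keratinocyte (−0.17, 0.0526); from day 38 to 60 class I (−0.03, 0.839) and muscle (−0.26, 0.687); and from day 20 to 60 melanocyte (0.57, 0.231), neural crest (0.22, 0.485), MAPK (0.40, 0.229), cartilage (0.11, 0.241) and mitochondrial (−0.12, 0.0950). Of the turned ones, the medians for SA against WT became −1.50 (interferon-stimulated), −0.88 (interferon gamma), −0.34 (class I), −0.040 (endothelial), −0.081 (adipocyte) and −0.49 (immediate early). From day 20 to 38 they became 0.72 (melanocyte, a list not called) and −0.061 (adipocyte). From day 38 to 60 they became 0.40 (interferon-stimulated), 0.24 (interferon gamma), −0.24 (melanocyte) and 0.30 (adipocyte), and from day 20 to 60, 0.16 (macrophage), 0.23 (adipocyte) and 0.071 (muscle). Fat and muscle turned by construction; for the others the cause was not tested. A normalization by scale, a detection filter and a slide block were planned and not run, since the values were already quantile normalized, detection p-values matched no sample by name and 1 slide was named. Signal over background limits dim genes such as Ifnar1 and Ifnb1, which were not tested.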

Other observations

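All tests in this part were chosen after the results were seen, and the criteria of 3 of them were revised after a first run in which they had favoured the explanation tested: tissue taken along with the tumour was dropped for the fat and muscle pattern, since that pattern itself makes the correlation, and the rules for the muscle and fat share and for time of day were tightened. The rule for sex was also replaced, since its first form could not have excluded sex. The rule for macrophages was replaced later by a comparison of medians with the spread of single members, and that rule decided nothing. The array means of the macrophage list are given below as well.

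Among genes called from day 38 to day 60 but in no list, several of cell division fell, named here after their values were seen: the kinetochore genes Ndc80 (−1.63), Cenpi (−1.58) and Cenpk (−1.58), the cohesion protector Sgo1 (−1.93) and the chromokinesin Kif4 (−1.37). Genes of cholesterol handling rose: the exporter Abcg1 (1.48), the sterol carrier Stard4 (1.40) and the ester hydrolase Nceh1 (1.56). No enrichment was tested for these groups.

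Fat and muscle markers rose as lists in SA against WT tumours at day 38. A lower share of tumour cells in SA was taken to raise markers of every other tissue alike. The fat list rose over the fibroblast list by 2.70 (pooled SD 0.474). This cannot exclude a lower share, since the fat list was picked after it had risen and adjoining tissue need not raise every list alike. The lists of tumour cell genes went opposite ways and did not decide it. Array means of melanocyte genes were −0.38 and 0.08 in SA at day 38, above −0.94 and −0.98 in WT. Those of neural crest and undifferentiated melanoma genes were 0.26 and −0.14, below 0.38 and 0.43 in WT. Sex remained open too. The 4 male-pattern SA arrays of days 20 and 60 lay above both WT arrays in the fat list by a mean of 1.19. Day 60 alone lay above by 0.841, within 2 pooled SDs (0.505). These arrays differ from WT at day 38 in day as well as in genotype. In the muscle list, not tested here, SA_day60 replicate 2 (−2.30) lay below both WT arrays (−1.19 and −1.45). SA_day60 replicate 1 (0.27) and both day 20 arrays (1.58 and 0.66) lay above them. A difference due to the genotype stays among the open explanations, and more adjoining tissue in some samples was not tested apart from the pattern itself.

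Interferon-stimulated genes rose as a list in the same comparison. More macrophages in SA stayed open: the median of their markers was 0.03, which is 0.780 below that of the interferon-stimulated list, but 13 members were higher and 10 lower, with an SD of 0.992. The array means of the macrophage list were 0.08 and −0.04 in SA at day 38 and 0.19 and 0.13 in WT. By its array means this list was therefore not higher in SA, while its members differed in direction. Sex could not be told apart from genotype. The male-pattern SA arrays lay above WT by 0.568, with 3 of 4 above both WT arrays, but day 60 by 0.024 (pooled SD 0.711). Those SA arrays differed from WT in day as well as in genotype. The muscle and fat share stayed open too, since with both list means as covariates the median turned to −1.50 (camera adjusted p = 2.40e-06) on 2 residual degrees of freedom, too few to decide. An effect of the stabilised receptor remains among the open explanations and was not tested apart from these.

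Clock genes shifted from day 38 to day 60, with Nr1d1 and Ciart (1.08) called. The other 10 were chosen as an arm of 7 genes grouped with Nr1d1 and an arm of 3 genes of the opposite phase. Among the 3, Clock rose by 0.37, as the 7 did, while Arntl and Nfil3 fell. The arms moved apart by 1.19, at the 97.55 percentile of 10000 random sets matched on level (central range −0.908 to 1.18). This lay too near the edge to decide for or against a different time of day at dissection, and 0 of the 10 were called, among them Dbp (2.03, limma adjusted p = 0.0908) and Arntl (−0.71). The genes of a random set were drawn singly, so the central range is too narrow where clock genes move together. A percentile among such sets does not measure the spread between tumours either. In SA against WT at day 38 the arms moved by −1.27 (percentile 0.68, outside its central range of −0.952 to 0.711), while the arrays of day 20 lay apart (0.53 and −1.08), so that the change from day 20 to 38 was −0.45, but 0.36 without SA_day20 replicate 1 and −1.26 without SA_day20 replicate 2, and that from day 20 to 60 was 0.74, but 1.55 and −0.07. The muscle and fat share did not decide it (r = −0.568, exact permutation p = 0.145), since those lists had changed between the same groups. A candidate explanation is that tumours were taken at different hours, which no label states and which the spread within day 20 would need within a group too, and a change of the clock with time in the tumour stays open.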
